A study of Caenorhabditis elegans with 2 samples.

How the data were processed

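The data came from 2 biological replicates of chromatin immunoprecipitation with sequencing (ChIP-seq) in whole first-stage (L1) larvae of Caenorhabditis elegans, of mixed sex. The strain carries an insertion that expresses ALY-2 fused to eGFP, in a background with an unc-119 mutation, per the labels. The labels name aly-2 as the antibody's target in one field and eGFP-tagged aly-2 in another, so the antibody itself is not given in the sources used here. ALY-2 belongs to the REF/ALY family of proteins that bind messenger RNA and take part in its export from the nucleus. Both replicates form 1 group, so no comparison between conditions was possible. The labels call them biological replicates and say no more of how the worm cultures were kept apart. The labels give a size range of 150 to 350 bp for the libraries.

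Per the labels and the description files deposited with each sample, the authors called peaks in each replicate and in both replicates together, each against a control alignment, and kept peaks and background peaks as input for the irreproducible discovery rate (IDR), a measure of how well ranked peaks repeat between replicates. They then deposited a final list thresholded on the IDR at the optimal setting. Every list was deposited on the ce10 and the ce11 genome builds. The aligner, the peak caller, their versions, the IDR threshold and the read depth are not given in the sources used here, and the control library was not used here. Each peak carries a signal value that the authors' caller gave it, on a scale that is not given, and a −log10 q-value, also from the authors. These values were used only to describe, rank or filter peaks within a list. Because depth is unknown, no interval on any single peak's signal was computed.

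The final ce11 list held 1446 peaks, and each was also found in the pooled list of 15675 peaks with the same position and signal. The final list was exactly the 1446 pooled peaks of highest signal. The remaining 14229 pooled peaks served as lower-signal peaks for comparison. Almost all peaks of a list had 1 fixed width, so width carries little information on the extent of binding. Final peaks were called over both replicates together and have no replicate error of their own. The spread was therefore taken from the 1446 peaks of highest signal in each replicate list, as mean ± SD with n = 2.

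Coordinates are given on ce11, whose chromosome names and lengths match the WBcel235 reference, and are counted from 1. Genes came from Ensembl release 115 and sequence from the RefSeq assembly, for the 6 nuclear chromosomes with 46890 genes, of which 19973 were protein-coding. Lists on ce10 were used for counts, widths and chromosome shares only. A promoter was the stretch from 1000 bp upstream to 200 bp downstream of the annotated 5′ end of a protein-coding gene. Each summit received 1 class, in the order promoter, 5′ UTR, coding sequence, 3′ UTR, exon of a non-coding gene, intron, within 500 bp downstream of a gene, and intergenic. Class shares were compared with 10000 random placements on the same chromosomes and, by Fisher's exact test, with lower-signal summits. Intervals on shares are exact (Clopper-Pearson) 95% intervals and cover counting error only. Where a list had 0 genes with a summit, the limit given is 3 counts out of its number of members.

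The number of genes with a final summit in the promoter window was compared with all other coding genes, or for non-coding lists with all other genes, by two-sided Fisher's exact tests adjusted over the 34 lists by the Benjamini-Hochberg method at 0.05. The lists were fixed before the data were examined and were built from gene name classes and biotypes. For microRNA genes the species prefix was removed from gene names first, as only 8 genes matched without that step. The chemoreceptor name pattern also took in other families, among them 6 serpin genes. All 30 spliced leader genes also belong to the small nuclear RNA list. A gene can share its summit with a neighbour, and genes in clusters are not independent. Overlaps between replicates needed at least 1 bp and were compared with 1000 random placements. The rank correlation of signals and the GC differences were tested with 100000 permutations, two-sided. The smallest p that these resamplings can give is 0.0002 for placements, 0.002 for overlaps and 1e-05 for permutations. The shares of peaks on the X chromosome and in the middle 50% of each autosome were tested by exact two-sided binomial tests against the share of coding 5′ ends. Sequence words of 6 bases in 200 bp around summits were compared by Fisher's exact test, each word pooled with its reverse complement.

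Genes were named by a rule written before the data were examined. It took the genes whose promoter window, or failing that gene body, held each of the 15 final peaks of highest signal, up to 4 members of each list past the test in order of signal, and aly-1, aly-2, aly-3 and unc-119. Where a summit lay in the windows of several genes, all were named, except that 1 summit of the chemoreceptor list is not reported here. Of the 73 summits named for the lists, 50 lay in the window of at least 1 further gene.

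The code was tested on simulated positions. Of 40 sets of random positions, a share of 0.05 gave a promoter share with p under 0.05. A simulated promoter share of 60% was recovered as 60%. All 5 gene lists given extra summits were recovered among 26 coding lists, and 1 list without them, the chemoreceptors, also passed as lower. All 300 shifted peaks were matched, 2 others were matched by error, and a simulated difference of 5 in mean GC was estimated as 4.59. Alternatives covered a stricter list, each replicate alone, other windows, other assignments of summits to genes, circular shifts of the peaks along chromosomes, other overlap rules and the ce10 list. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.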

Results

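Peaks of eGFP-tagged ALY-2 in L1 larvae were deposited as 1 final list for 2 biological replicates, with a pooled list and a list per replicate. The question that the design poses is where in the genome the tagged protein was recovered with chromatin. The final ce11 list held 1446 peaks, against 26798 peaks in replicate 1 and 25463 in replicate 2. Those longer lists include background peaks, and the depth of the libraries is unknown. Final peaks covered 513424 bp, or 0.512% of the nuclear genome, and 1419 of them were 360 bp wide. The authors' signal ranged from 42.7 to 515, with a median of 58.8. Chromosome III held 310 final peaks and chromosome I 312, or 11.7 and 10.8 per 100 coding genes. Chromosome V held 221 peaks, or 4.43 per 100 coding genes. The ce10 final list held 1372 peaks with the same modal width of 360 bp, of which 9.84% lay on X, against 10.03% on ce11.

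The peak of highest signal lay upstream of cdc-48.1, which encodes an AAA ATPase of the p97 family, on chromosome II from 10563457 to 10563670, and was ranked 1 in both replicates. Its summit also lay in the window of the snoRNA gene C06A1.9. The next peak, with a signal of 328, lay on chromosome IV from 17281226 to 17281523, with its summit 51 bp past the 3′ end of hsp-1, a gene for a constitutive Hsp70 chaperone. The peak ranked 3, on chromosome II from 11756879 to 11757226, had its summit 50 bp past the 3′ end of F44E5.4. It was ranked 30 in replicate 1 and 2 in replicate 2. The peak ranked 4, on chromosome V from 724006 to 724463, lay in the promoter window of fbxb-72 and 144 bp past the 3′ end of icl-1, which encodes an enzyme of the glyoxylate cycle. This peak was ranked 18 in replicate 1 and 3 in replicate 2. The peak ranked 5 lay in the windows of gasr-8, C47E8.11 and the tRNA gene WBGene00014287.

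Ribosomal protein and spliced leader genes filled the next ranks. Peaks upstream of rpl-20, rpl-3 and rpl-35 had signals of 289, 272 and 268. The rpl-20 summit also lay in the window of Y17G9B.5. Peaks at sls-2.4, sls-2.1 and sls-2.2, genes for the SL2 spliced leader RNA, had signals of 308, 248 and 247. They also lay in the windows of egg-5 and R12E2.18, of H41C03.3, and of C17C3.22 and C17C3.23. The sls-2.4 summit lay 251 bp past the 3′ end of R12E2.11, and the sls-2.1 summit 230 bp past that of nep-25. Spliced leader genes have near-identical copies, so the share of reads that belongs to each is uncertain. The peak ranked 12 was intergenic on X, and the peak ranked 13 lay in an intron of Y41G9A.17 on X. The peak ranked 14 lay in the window of pmp-2, with its summit 58 bp past the 3′ end of acer-1. The peak ranked 15 lay 55 bp past the 3′ end of F19H6.6. Of these 15 peaks, 9 were in coding promoters and 4 were outside every gene body and promoter window.

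Nearly every final peak, including those at cdc-48.1, hsp-1 and rpl-3, was found in both replicates, whereas weaker peaks repeated less often. Of the 1446 final peaks, 1442 (99.7%) overlapped a peak in each replicate list. Of the pooled peaks ranked 10001 and lower, 40.1% did. Among the 1446 peaks of highest signal in each replicate, 905 (62.6%) of those in replicate 2 overlapped 1 in replicate 1, against 1.14% for random placements (permutation p = 0.002, the smallest possible). For the whole lists the share was 47.8%, against 18.1% for random placements (permutation p = 0.002). The signals of the 1442 peaks correlated with Spearman's rho = 0.444 across peaks (permutation p = 1e-05, the smallest possible). Peaks are not independent replicates, and both lists were inputs to the choice of final peaks.

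**Figure D1:**
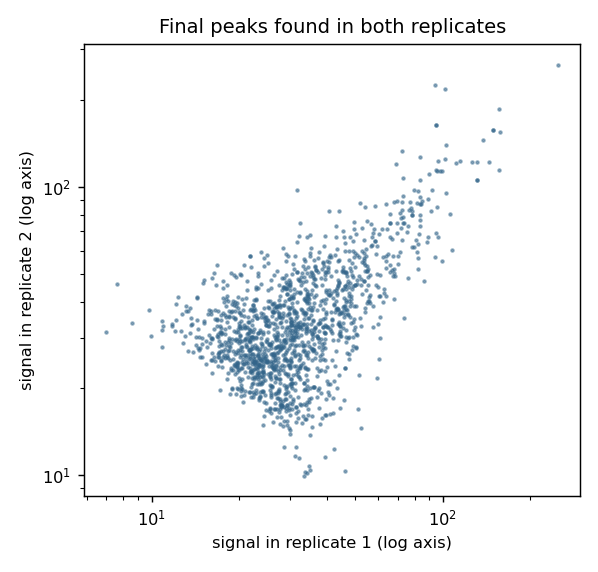
The authors' signal in replicate 1 (x axis, log scale) and in replicate 2 (y axis, log scale), with 1 point for each of the 1442 final peaks found in both lists. Signals rise together with wide scatter (rho = 0.444).

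Final summits lay mainly just upstream of coding genes, and were scarce in coding sequence and introns. In promoters lay 817 summits, or 56.5% (exact 95% interval 53.9 to 59.1), against 21.4% of random positions and 27.02% of lower-signal summits. The replicates alone gave 52.9% ± 1.32 (SD, n = 2). Introns held 11.9% of final summits, against 32.3% of random positions, and coding sequence 5.95%, against 20.1%. The summits in promoters lay at a median position of -182 bp from the nearest annotated 5′ end. Of these summits, 90.5% were upstream of it, in a window that itself reaches 1000 bp upstream but only 200 bp downstream. They fell in the windows of 1115 coding genes, or 5.58% of all coding genes, and 291 of the 817 summits lay in more than 1 window.

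Gene ends and non-coding exons were the other classes above random. The 3′ UTR class held 5.95% of final summits against 2.36% of random positions, and the 500 bp downstream of genes held 9.34% against 5.84%. Exons of non-coding genes held 4.29% against 2.43%. Intergenic positions held 5.39% against 14.8%. The promoter, coding, 3′ UTR, non-coding exon, intron, downstream and intergenic shares each differed from random placement (adjusted permutation p = 0.000229, from the smallest p the placements can give), and the 5′ UTR share of 0.692% did not (adjusted permutation p = 0.780). Against lower-signal summits, the 3′ UTR share did not differ (5.28%, Fisher's exact test, adjusted p = 0.308), and the downstream share was higher (7.67%, adjusted p = 0.0360). A summit near a 3′ end may also lie in a promoter window of a neighbouring gene, which takes precedence in this classification.

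**Figure D2:**
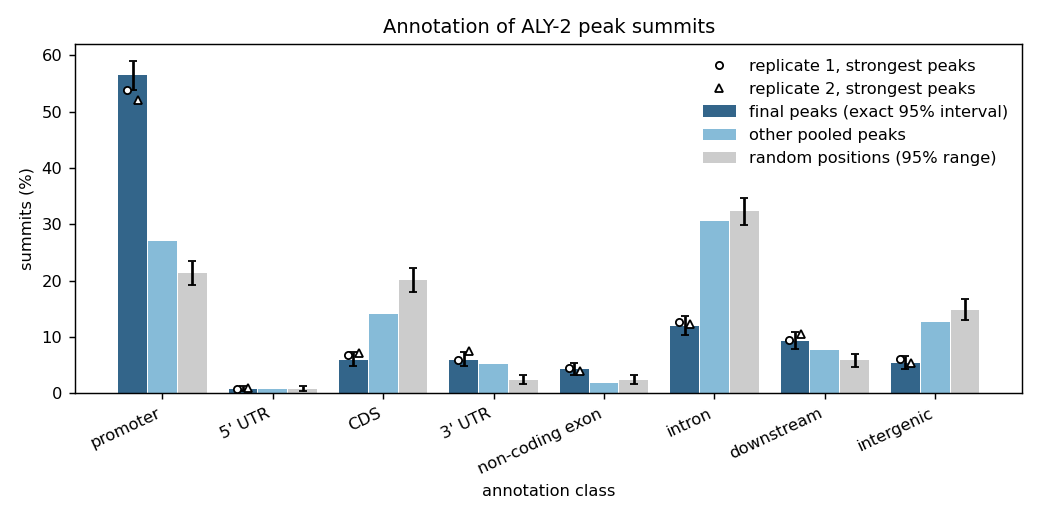
Share of summits (y axis, percent) in 8 annotation classes (x axis) for final peaks, lower-signal pooled peaks and random positions, with exact 95% intervals on final peaks and 95% ranges of placements on random positions. Circles and triangles are the strongest peaks of replicates 1 and 2. Promoters hold 56.5% of final and 27.02% of lower-signal summits.

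**Figure D3:**
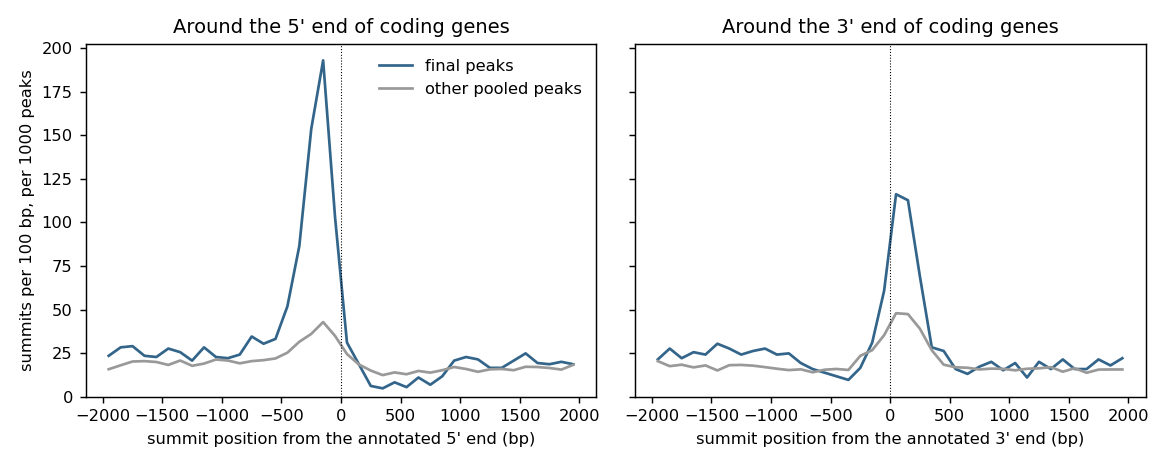
Summits per 100 bp and per 1000 peaks (y axis) by position from the annotated 5′ end (left) and 3′ end (right) of coding genes (x axis, bp, negative values upstream), for final and lower-signal pooled peaks. Final summits peak just upstream of 5′ ends, with a smaller peak just past 3′ ends.

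Genes for the protein synthesis machinery carried final peaks more often than other coding genes. No control library or other tagged protein was used here, so whether recovery at these or the other promoters, tRNA and snoRNA genes was particular to ALY-2 was not assessed. Every coding list that was higher at final peaks was also higher among lower-signal summits (Fisher's exact tests adjusted over the 26 coding lists). These calls were thus not particular to final peaks. The odds ratio was lower there for each of these lists except nucleoporins, as with 2.87 against 28.5 for cytosolic ribosomal proteins. For nucleoporins it was 6.33 against 6.26. Of 81 cytosolic ribosomal protein genes, 50 (61.7%, exact 95% interval 50.3 to 72.3) had a final summit in the promoter window, an odds ratio of 28.5 (Fisher's exact test, adjusted p = 3.79e-41). Each replicate alone gave 47 of 81. The strongest were rpl-20, rpl-3, rpl-35 and rpl-15, the last with a signal of 209 at a summit shared with the snoRNA genes K11H12.12 and K11H12.13 and with K11H12.8. Translation factor genes had a summit in 14 of 40 cases (exact adjusted p = 7.56e-08), led by iff-2, eef-1A.1, eef-2 and eif-3.B with signals of 138, 133, 110 and 105. The iff-2 summit was shared with F54C9.12 and F54C9.14, that of eef-1A.1, a gene for elongation factor 1 alpha, with rfc-4 and mir-5549, and that of eef-2 with clsp-1. Mitochondrial ribosomal protein genes had a summit in 15 of 70 cases (21.4%, exact adjusted p = 1.78e-05), with mrps-7, mrpl-28, mrpl-12 and mrpl-55 strongest. The mrps-7 summit was shared with Y57G11C.3, and that of mrpl-12 with Y39A1A.21 and Y39A1A.22. Aminoacyl-tRNA synthetase genes passed with 5 of 32 (exact adjusted p = 0.0437), among them fars-1, mars-1, fars-3 and kars-1. The fars-1 summit was shared with rbm-5, and that of mars-1 with F58B3.6. The synthetase call was lost without replicate 1 (exact adjusted p = 0.109), in the upper 50% of peaks by signal (0.328), with the 500 bp window (0.0890) and with each summit given to its nearest 5′ end alone (0.0755), and without replicate 2 the odds ratio of translation factors fell from 9.21 to 6.03.

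Genes for protein folding, turnover and energy supply were also higher. Heat shock protein and chaperonin genes had a summit in 15 of 59 cases (25.4%, exact adjusted p = 2.15e-06), led by hsp-110, cct-1, cct-8 and hsp-60 with signals of 210, 190.0, 177 and 155. The summit of hsp-110 was shared with the proteasome gene rpn-3 and C30C11.14, that of cct-1 with mig-5, that of cct-8 with Y55F3AR.2 and that of hsp-60 with Y22D7AL.10. Proteasome genes had 9 of 33 (27.3%, exact adjusted p = 0.000152), with rpt-2, pbs-1 and rpn-9 after rpn-3. The rpt-2 summit was shared with aps-1 and F29G9.10, that of pbs-1 with K08D12.3 and that of rpn-9 with T06D8.9. Respiratory chain and ATP synthase genes had 12 of 37 (32.4%, exact adjusted p = 1.85e-06), with cox-5A, cox-5B, atp-3 and atp-2 strongest. The cox-5B summit was shared with F26E4.14 and F26E4.16, that of atp-3 with F27C1.2, F27C1.16 and F27C1.17, and that of atp-2 with C34E10.10 and C34E10.12. Vacuolar ATPase genes had 5 of 20 (exact adjusted p = 0.00701), among them vha-8, vha-12, vha-2 and vha-1. The vha-8 summit was shared with C17H12.2, that of vha-2 with R10E11.6 and that of vha-1 with sqv-3. The proteasome call was lost in the upper 50% of peaks by signal (exact adjusted p = 0.116), with an odds ratio of 3.22 without replicate 2 against 6.39. The heat shock protein call was lost by nearest 5′ end (exact adjusted p = 0.0692).

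Genes that act on messenger RNA, and nucleoporin and cell cycle genes, were higher as well. Splicing factor genes had a summit in 16 of 47 cases (34.04%, exact adjusted p = 1.32e-08), with lsm-5, snr-4, snrp-3 and prp-40 strongest. The snr-4 summit was shared with T11F9.15, C52E4.14 and the piRNA gene 21ur-10927, and that of prp-40 with clu-1. The mRNA export and exon junction list, which includes the tagged gene itself, had 5 of 16 (31.3%, exact adjusted p = 0.00250). Its strongest members were thoc-7 of the THO complex, nxt-1, aly-2 and hel-1, with signals of 97.9, 77.8, 64.5 and 60.9. The thoc-7 summit was shared with rpl-29, that of hel-1 with C26D10.4 and that of aly-2 with daf-10 and rpb-12. Nucleoporin genes had 7 of 26 (26.9%, exact adjusted p = 0.000908), led by npp-3, npp-19, npp-12 and npp-14. The npp-3 summit was shared with top-2, that of npp-12 with T23H2.3 and that of npp-14 with cel-1. Cell cycle and replication genes had 5 of 25 (exact adjusted p = 0.0173), with cdc-6, efl-1, lin-35 and cyb-1 strongest. The cdc-6 summit was shared with acin-1, that of lin-35, the retinoblastoma homologue, with vps-51, and that of cyb-1 with orc-5. Without replicate 1 the mRNA export list fell to 3 of 16, with an odds ratio of 4.32 against 7.72 (exact adjusted p = 0.0660), and by nearest 5′ end that call (exact adjusted p = 0.0540) and the cell cycle call (0.132) were lost. The cell cycle call was also lost without replicate 2 (exact adjusted p = 0.0571), and the nucleoporin call in the upper 50% of peaks by signal (exact adjusted p = 0.273).

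Small structural RNA genes carried final peaks often. Of 346 snoRNA genes, 98 (28.3%, exact 95% interval 23.6 to 33.4) had a summit in the window, an odds ratio of 11.6 (Fisher's exact test, adjusted p = 6.83e-59). The replicates alone gave 25.9% ± 1.43 (SD, n = 2). Besides C06A1.9, K11H12.12 and K11H12.13, the strongest was F54E7.10, whose summit was shared with rps-12, ska-3 and F54E7.11. Spliced leader genes had 7 of 30 (exact adjusted p = 0.000152), including sls-2.8, whose summit was shared with tim-1, Y75B8A.23 and Y75B8A.49. The small nuclear RNA list, which holds all spliced leader genes, had 16 of 129 (exact adjusted p = 3.31e-05), with R07E5.16 ranked next after sls-2.4, sls-2.1 and sls-2.2. Transfer RNA genes had 69 of 612 (11.3%, exact adjusted p = 1.13e-16), led by WBGene00014287, WBGene00023221, WBGene00023110 and WBGene00023111. The WBGene00023221 summit was shared with ZK994.7, and the last pair shared 1 summit with M02F4.12. Transfer RNA genes also have near-identical copies. The microRNA list passed with 16 of 260 (6.15%, exact adjusted p = 0.0388), including mir-354, mir-5549, mir-54 and mir-55. The mir-354 summit was shared with rps-20 and ekl-4, and mir-54 and mir-55 shared 1 with mir-56 and F09A5.11. The microRNA call was lost without replicate 2 (exact adjusted p = 0.0770), and when piRNA genes were left out of the comparison genes (exact adjusted p = 0.506), a setting chosen after seeing the data. It was also lost in the upper 50% of peaks, with the 500 bp window, by nearest 5′ end and with clusters counted once, and the odds ratio of spliced leader genes was 12.99 without replicate 1 against 8.45. The comparison genes of these lists include the piRNA genes, 0.391% of which had a summit, and this raises the odds ratios in this paragraph. With piRNA genes left out, the snoRNA, spliced leader, small nuclear RNA and transfer RNA calls were kept.

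Chemoreceptor, C-type lectin, cytochrome P450 and UDP-glucuronosyltransferase, F-box, nuclear hormone receptor, and neuropeptide and insulin genes had final peaks less often than other coding genes, and piRNA genes less often than all other genes. Chemoreceptor genes had a summit in 7 of 1365 cases (0.513%, odds ratio 0.0814, Fisher's exact test, adjusted p = 6.22e-25). Among them were sri-5, whose summit was shared with rsr-1, and srg-45. C-type lectin genes had 0 of 240 (exact adjusted p = 5.08e-06), which allows a share of up to 1.25%, and cytochrome P450 and UDP-glucuronosyltransferase genes 0 of 141 (adjusted p = 0.00123), which allows up to 2.13%. F-box genes had 4 of 322 (exact adjusted p = 0.000262), namely fbxb-72, fbxb-85, fbxb-58 and fbxa-137. The fbxb-85 summit was shared with hex-3. Nuclear hormone receptor genes had 4 of 269 (exact adjusted p = 0.00221), namely nhr-49, nhr-1, nhr-47 and nhr-59. The nhr-47 summit was shared with dnj-19, C24G6.10 and C24G6.12, and nhr-59 shared 1 with fbxa-137. Neuropeptide and insulin genes had 1 of 140 (exact adjusted p = 0.00810), ins-39. The piRNA genes, most of which lie in clusters, had 60 of 15363 (exact adjusted p = 4.40e-194), among them 21ur-3995 and 21ur-3824 at a summit shared with dld-1 and LLC1.120, 21ur-13032 with T04C12.26, and 21ur-13616 with eelo-2. In the upper 50% of peaks by signal the neuropeptide, F-box and P450 calls were lost, by nearest 5′ end the neuropeptide call, and with clusters counted once the nuclear hormone receptor call (exact adjusted p = 0.0540). The odds ratio of nuclear hormone receptors was 0.138 without replicate 1 and 0.406 without replicate 2, against 0.253. That of F-box genes was 0.115 without replicate 1, against 0.210. Among lower-signal summits, chemoreceptor, F-box and C-type lectin genes were lower too. Nuclear hormone receptor (19.7% against 20.2% of other coding genes, exact adjusted p = 0.914), P450 (17.7%, 0.624) and neuropeptide (13.6%, 0.0783) genes did not pass there. For these 3 lists, a lower share past the test was seen at final and not at lower-signal peaks.

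No difference from other genes passed the test for histone (3 of 72), ceh homeobox (2 of 63), cuticle collagen (3 of 156, exact adjusted p = 0.0694), major sperm protein (0 of 31), germline (2 of 35), muscle (0 of 28), neuronal (0 of 23), intestine (0 of 20), ribosomal RNA (0 of 20) and long non-coding RNA (6 of 294) genes. Counts of 0 allow shares of up to 9.68% for major sperm protein, 10.7% for muscle, 13.04% for neuronal, and 15% for intestine and ribosomal RNA genes. Ribosomal RNA genes had 0 of 20 among lower-signal summits too. Whether reads could be placed at them was not assessed, so their count of 0 is not a measured absence. Among lower-signal summits, muscle genes were higher (12 of 28, 42.9%, exact adjusted p = 0.0139) and major sperm protein genes lower (1 of 31, exact adjusted p = 0.0208). The other coding lists of this paragraph did not pass there. The ceh homeobox list had 1 of 63 without replicate 1, an odds ratio of 0.301 against 0.554 (exact adjusted p = 0.475). Collagen genes were lower without replicate 2 (0 of 156, exact adjusted p = 0.00102) and in the upper 50% of peaks by signal (0 of 156, exact adjusted p = 0.0317). Long non-coding RNA genes were lower when piRNA genes were left out of the comparison genes (exact adjusted p = 0.0220), a setting chosen after seeing the data. In total, 17 lists were higher and 7 lower among 34. Under circular shifts of the peaks, which compare each list with the genome rather than with other genes and keep clusters together, the 17 higher lists all passed and 2 of the 7 lower lists did, the chemoreceptor and piRNA genes.

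**Figure D4:**
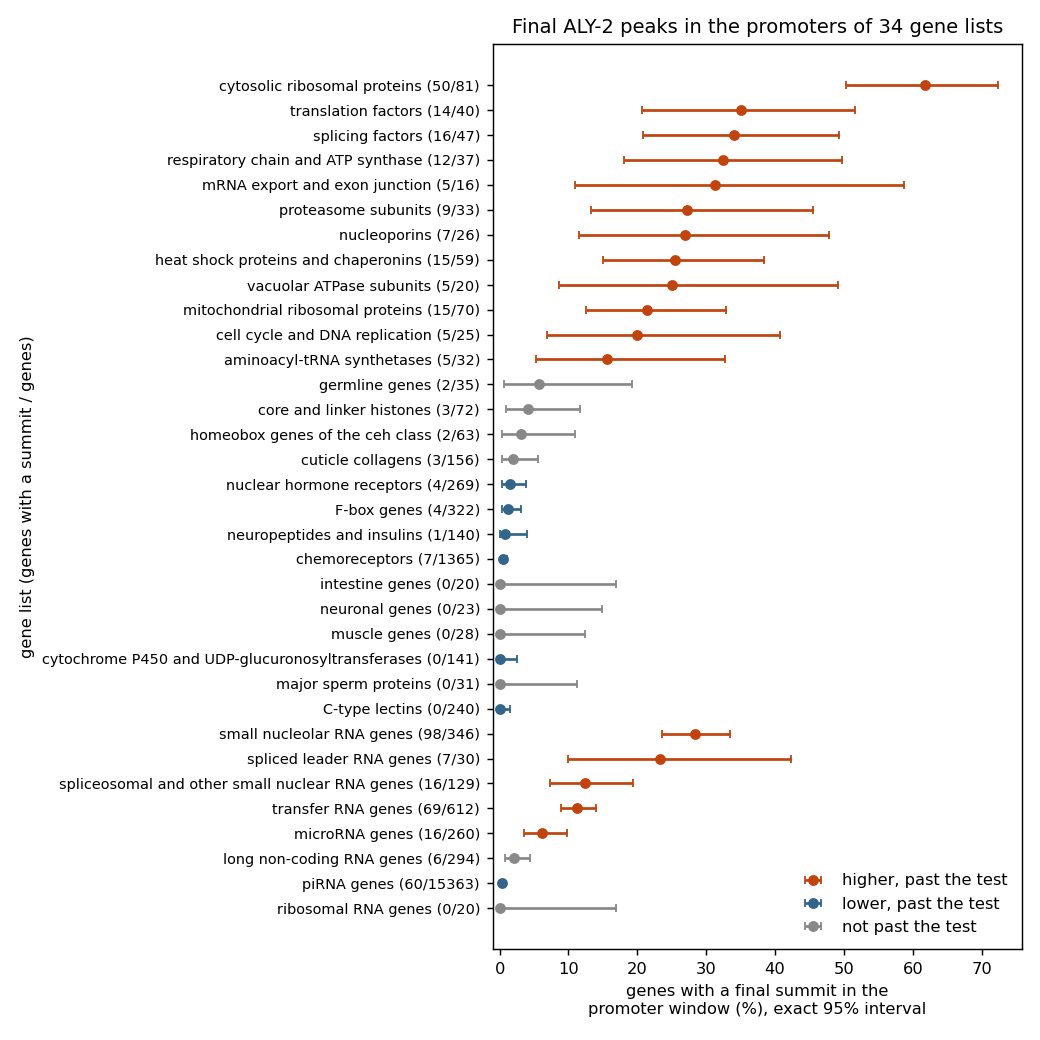
Share of genes with a final summit in the promoter window (x axis, percent, with exact 95% intervals) for each of 34 gene lists (y axis, with genes holding a summit and all genes), coloured by direction and by whether the adjusted Fisher's exact test passed. Cytosolic ribosomal protein genes (50 of 81) stand highest, and C-type lectin genes have 0 of 240.

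The tagged gene itself had 1 final peak in its promoter. The aly-2 gene lies on chromosome IV from 9147468 to 9148579, and the summit lay at 9147125 with a signal of 64.5, ranked 585. The promoter also held a peak ranked 522 in replicate 1 and 1 ranked 1157 in replicate 2. No other final peak lay within 20 kb of aly-2, while the strongest peaks of each replicate alone included 2 there. The related genes aly-1 and aly-3 on chromosome IV, and unc-119 on chromosome III, the gene mutated in the strain background, had 0 final peaks within 20 kb. The strain carries an inserted tagged copy, and its position was not used here.

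The X chromosome held fewer final peaks than its coding genes would give, and the centres of autosomes held more. The lower yield was not particular to X: chromosome V held 4.43 final peaks per 100 coding genes and X 5.31, while the other chromosomes held 6.38 or more. Of the chromosomes, X alone was tested. On X lay 145 of 1446 peaks, or 10.03% (exact 95% interval 8.53 to 11.7), against 13.7% of coding 5′ ends (exact binomial test, p = 3.45e-05). Of lower-signal peaks, 15.3% lay on X, and the replicates alone gave 10.7% ± 0.880 (SD, n = 2). In the upper 50% of final peaks by signal, the X share was 11.2% and no longer passed (exact binomial test, p = 0.0579). In the centres of autosomes lay 812 of 1301 peaks, or 62.4% (exact 95% interval 59.7 to 65.1), against 55.7% of coding 5′ ends (exact binomial test, p = 8.74e-07). Of lower-signal peaks, 60.9% lay there, and the replicates alone gave 61.6% ± 0.334 (SD, n = 2).

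Sequence at final summits was richer in G and C than at lower-signal summits, in promoters and outside them. Mean GC content over 200 bp was 39.9% at final and 34.8% at lower-signal summits, a difference of 5.05 percentage points (permutation p = 1e-05, the smallest possible). For promoter summits alone the difference was 4.42, and outside promoters 5.61 (permutation p = 1e-05 for each). The nuclear genome averages 35.4%. Of 2080 words of 6 bases, 613 were more and 429 less frequent at final summits. The word GACGCA, with its reverse complement, was present at 19.8% of final and 6.002% of lower-signal summits (Fisher's exact test, adjusted p = 2.04e-58). In promoters alone, GCGCCA led with 17.7% against 4.16% (exact adjusted p = 5.24e-33). Word frequencies follow GC content, which was not held equal between the sets.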

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

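The alternatives without either replicate for base composition, annotation classes and the tagged locus, the comparison without piRNA genes, the chemoreceptor list without other families, and the correlation over all pooled peaks were chosen after seeing the data. Of the alternatives to the main results, 67 gave the same direction and side of the threshold or a count within the set range, 1 was weaker, 1 reversed and 4 moved, and of those to single genes and lists 523 did, with 26 weaker, 3 stronger, 12 reversed and 22 moved. Using the top of the pooled list changed nothing because it is the final list, and its outcomes are among those counted as the same. Lists left unaltered by the settings without piRNA genes or without other families are counted too, though their outcome could hardly change. The promoter share stayed between 34.6% with the narrowest window and 69.5% with all genes, above random in each. The X share was 11.2% and no longer past the test in the upper 50% of peaks, where the share was nearer to that of coding genes and fewer peaks were tested. Under circular shifts 2 lists were lower in place of 7, and as those shifts both compare with the genome and keep gene clusters together, the cause was not tested. Within 50 kb of aly-2 lay 2 final peaks, and without replicate 1 or replicate 2 the count within 20 kb was 2 in both. The 5′ UTR share ranged from 0.692% to 0.968% without either replicate and crossed the random share, past the test in neither. Some lists changed direction, none of them past the test in the setting where the direction changed, with these odds ratios. Without either replicate in turn, histones ranged from 0.812 to 1.06, muscle genes from 0 to 1.38 and long non-coding RNA genes from 0.626 to 1.09. Germline genes gave 0.591 with the 500 bp window and 0.645 by nearest 5′ end, where major sperm proteins gave 1.52. Histones gave 1.88 with clusters counted once. As ratios to circular shifts, histones gave 2.83, ceh homeobox genes 2.02, collagens 1.17 and long non-coding RNA genes 1.21, and nuclear hormone receptors, lower in the main test, gave 1.04. Apart from the causes given, the cause was not tested. Of 82 genes named for the lists, 76 kept a summit without replicate 1, 79 without replicate 2 and 72 in the upper 50% of peaks. Depth is unknown, so what it limits was not assessed.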

Other observations

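The 3′-end gene lists with either set of summits, the comparison of long genes, and the tests of neighbouring promoters, of short genes and of repeated sequence were chosen after the results were seen. The share of repeated summits replaced a filter that had removed 1 of 441 summits. Cuticle collagen, heat shock and chaperonin, and vacuolar ATPase genes carried final peaks at their 3′ ends, outside promoter windows, more often than other coding genes. Among final summits outside coding promoters, those from 200 bp before to 500 bp past a 3′ end marked 342 coding genes. They marked 280 when only the 441 summits in no gene's promoter window were counted. A gene whose 3′ end lies within a neighbour's promoter window could not be marked there, yet stayed among the compared genes. How close the 3′ ends of each list lie to neighbouring promoters was not held equal, so it may contribute to these differences. Collagen genes were 11 of 156 in the wider set (exact adjusted p = 0.000525) and 9 of 156 in the narrower (exact adjusted p = 0.00237), among them col-117, col-3 and col-147, while 3 had a promoter summit. Heat shock and chaperonin genes were 7 of 59 (exact adjusted p = 0.000525) and 6 of 59 (exact adjusted p = 0.00151), including hsp-1 and hsp-3. Vacuolar ATPase genes were 5 of 20 (exact adjusted p = 0.000233) and 4 of 20 (exact adjusted p = 0.00151), including vha-12 and vha-14.

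Muscle, translation factor and cytosolic ribosomal protein genes passed the test at 3′ ends in the wider set and not in the narrower, and the difference between the sets was not tested. Muscle genes were 5 of 28 (odds ratio 12.6, exact adjusted p = 0.000528) and 1 of 28, act-4 (odds ratio 2.61, exact adjusted p = 0.425). The summits at act-1, act-2 and act-3 also lay in windows of non-coding RNA genes, T04C12.27 and T04C12.29, T04C12.14 and T04C12.15, and T04C12.26 and the piRNA gene 21ur-13032, and that at unc-45 in the window of the snoRNA gene F30H5.4. For translation factor genes the odds ratio was 6.44 (4 of 40, exact adjusted p = 0.0206) and 5.75 (3 of 40, exact adjusted p = 0.0683). For ribosomal protein genes it was 3.82 (5 of 81, exact adjusted p = 0.0412) and 3.69 (4 of 81, exact adjusted p = 0.0730). Chemoreceptor genes were lower in both sets, with 4 of 1365 (exact adjusted p = 3.07e-05) and 2 of 1365 (exact adjusted p = 2.60e-05). F-box genes were 0 of 322 in both sets (exact adjusted p = 0.0280 and 0.0730). Genes were named here after their values were seen.

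Genes of at least 2000 bp with a 3′-end final summit had a promoter final summit in 39 of 218 cases (17.9%), against 5.95% of the other long genes (Fisher's exact test, p = 1.47e-09).

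The 3′-end pattern was set against 3 technical explanations, and no biological explanation was tested, as the design has 1 group. Promoters of neighbouring genes are argued against: of 441 final summits in no gene's promoter window, 201 (45.6%) lay at coding 3′ ends, 4.4 times the random share of 10.4%, whose upper bound was 13.6%. Of lower-signal summits in no gene's promoter window, 17.9% lay at coding 3′ ends, so part of the excess over random positions was shared by weaker peaks. Spread of promoter signal along short genes is argued against as the only source by a ratio of 5.53 at 3′ ends of genes of at least 2000 bp. Shorter genes were not in that test. For those with a promoter summit as well, such as rpl-3 and vha-2, spread stays open. Of the 201 summits at 3′ ends, 0 had a repeated sequence of 36 bases over most of their 200 bp (exact upper bound 1.82%). Few final summits had one anywhere, 6 of 1446 in all and 4 of 629 outside promoters, so this outcome was nearly fixed in advance. The values argue only against reads shared between exact copies. Copies that differ by a few bases are not covered, and the read length is unknown. Recovery of any chromatin at strongly transcribed genes, whatever the protein tagged, may contribute and stays open, because no control library and no other tagged protein was used here.

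The snoRNA excess was weighed against shared windows and shared reads, and no biological explanation was tested. Of 191 snoRNA genes whose window overlaps no coding promoter window, 45 had a final summit, 12.7 times the number under circular shifts (3.56, upper bound 8; permutation p = 0.0002, the smallest possible), so coding promoters do not account for all of it. Repeated sequence was seen at 0 of 93 summits in snoRNA windows (exact upper bound 3.89%). It was seen at only 6 of all 1446 final summits, so this outcome was nearly fixed and shared reads were hardly tested. Many snoRNA genes lie in introns or near other non-coding genes, whose promoters were not separated here and could be the source of part of the 12.7-fold excess. Coding 3′ ends were not separated either, and some 3′-end summits, such as those at unc-45 and vha-8, lay in snoRNA windows.

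The lower yield on X, with 5.31 final peaks per 100 coding genes against 4.43 on chromosome V, was weighed against a lower yield from the whole chromosome and against gene content, and no biological explanation was tested. Outside promoters the odds of X among final against lower-signal summits were 0.871 (95% interval 0.692 to 1.09), and in promoters 0.470 (0.352 to 0.627), without overlap, which argues against a loss of all X peaks alike. Among coding genes in none of the higher lists, the odds of a promoter summit on X against autosomes were still 0.350 (Fisher's exact test, p = 2.34e-17), against 0.332 among all coding genes. Those lists alone do not account for the lower yield. They hold only 18 of 2731 coding genes on X, so leaving them out could move the odds little. Among genes in the higher lists, 5 of 18 on X and 153 of 468 on autosomes had a summit, an odds ratio of 0.792 (0.277 to 2.26, Fisher's exact test, p = 0.801), an interval too wide to tell. Gene content beyond the lists, such as a smaller number of broadly expressed genes on X, may be a candidate explanation and was not tested.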
